A study of Caenorhabditis elegans with 2 samples.

How the data were processed

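Whole L1 larvae of strain OP321 were profiled by ChIP-seq against the tagged tlp-1 product in 2 biological replicates, with fragments of 150 to 350 bp per the labels. The files used were the authors' deposited lists of regions for ce10 and ce11, namely 1 list per replicate and 1 pooled list before thresholding, and 1 list thresholded by irreproducible discovery rate (IDR). The deposited lists give each region a signal value, made by the authors from the alignments of the libraries and a control; the signal has no stated scale and differs in scale between lists. They also give a -log10 q value, which the authors computed. Its maximum in the pooled list was 1.35, shared by 233 regions, so that no region had a stronger q and regions were ordered by signal. The summit offset of each region in the deposited lists was used as its position. The aligner, the peak caller and the IDR threshold were not given in the sources used here, and the control library was not analysed here. The thresholded ce11 list was checked to hold exactly the 328 regions of highest signal in the pooled list, 2.82% of it, with a lowest signal of 38.2. Read counts are not part of the lists, so the depth per library is unknown and no interval for a single peak's signal was computed.

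The 2 replicates formed the single group of the series, so no groups were compared. Thresholded peaks were compared with the other regions of the pooled list, which are the regions that could have passed the authors' threshold. Work on genes and sequence used ce11 with the annotation of Ensembl release 115. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The comparisons, the gene lists, the motifs, the rule for named genes and most alternatives were fixed before the data were examined; what was added later is named where it is given.

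The replicates were compared by the overlap, of at least 1 bp, of their 328 regions of highest signal, against 1000 pairs of random draws (one-sided permutation test). They were also compared by Spearman's correlation of signal over overlapping pairs with a bootstrap interval from 200 resamplings of pairs, and by an IDR fit, a Gaussian copula mixture of 2 components, at a threshold of 0.02. Recovery of thresholded peaks is given with exact 95% Clopper-Pearson intervals. Summit positions were classed as promoter (500 bp upstream to 200 bp downstream of a protein-coding TSS), coding exon, UTR, intron, other gene or intergenic. Classes, the 7 chromosomes and non-coding RNA genes within 1000 bp of a summit (tRNA, rRNA, snRNA, snoRNA and miRNA) were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family at 0.05. A count of 0 in a table was met by adding 0.5 to each cell for the odds ratio alone.

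Each summit was assigned the nearest protein-coding TSS within 2000 bp. The 24 gene lists covered Wnt signalling, Hox genes and cofactors, the T cell lineage and male tail, seam and epidermal regulators, cuticle collagens, heterochronic genes, pan-neuronal genes, neuronal identity factors and genes of the intestine, body wall muscle and pharynx. They further covered the germline and P granules, ribosomal proteins, histones, translation factors, heat shock and stress, the insulin pathway and L1 arrest, and the cell cycle. The last were nuclear hormone receptors, homeobox, bHLH, T-box and GATA genes, the miRNA pathway and Argonautes, and chromatin regulators. Each was tested against the genes assigned to any pooled region. The names dmd-1, lep-5 and lin-4 matched no protein-coding gene of the annotation and were left out. The 14 motifs were searched on both strands within 50 bp of the summit, against 5 GC-matched windows per peak from the other pooled regions; mean GC content was 33.8% in both sets. Named genes were those nearest the 25 thresholded peaks of highest signal, up to 4 members of each gene list by signal, tlp-1 and unc-119, and the genes at the 2 peaks of highest signal for each non-coding class. A nuclear peak with a second protein-coding TSS within 2000 bp was named with both genes where it is first named. Mitochondrial peaks were named by the nearest gene alone.

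The statistics were tested on simulated data. The IDR fit recovered 70.9% of consistent pairs where these made up 10% of all pairs, with 2.41% of calls false, and 81.0% where they made up 30%, with 1.42% false. It called 0 pairs when ranks were unrelated. The simulated consistent pairs lay further from the rest than those fitted to the data, whose mean was 1.18. The shares recovered and the shares of false calls therefore do not carry over to the data. The gene list test found 100% of simulated lists of 20 genes with 30% of them planted at peaks, with 4.31% of calls false; shorter lists were not simulated. The motif test found a motif planted in 10% of the windows in 100% of the simulations.

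Alternatives were the ce10 lists, stricter overlap, other numbers of top regions, other IDR thresholds, the higher-signal 50% of the peaks and each replicate alone. Others were the region midpoint, a wider promoter, other distances to genes, all genes within reach, all protein-coding genes as background, random draws of regions, flanks as motif controls, wider motif windows and chromosome length as reference. Gene context was not computed on ce10, for which no annotation was used here.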

Results

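Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on whole L1 larvae of the Caenorhabditis elegans strain OP321, whose insertion wgIs321 carries tlp-1 tagged with eGFP in an unc-119 mutant background. The gene tlp-1 encodes a C2H2 zinc finger protein known from the asymmetric division of the T blast cell and from the shaping of the male tail tip. The libraries formed a single group of 2 biological replicates of mixed sex, and the question they address is where the tagged protein sits in the genome at this stage. Because no region was called at the tagged gene itself, they are named here the libraries labelled tlp-1. On the ce11 build, the lists before thresholding held 28183 regions for replicate 1, 23975 for replicate 2 and 11633 for both replicates pooled. The thresholded list held 328 peaks, 303 of them on nuclear chromosomes. No read counts stand in the lists, so the depth is unknown, and the intervals of shares are exact binomial intervals that cover counting error over peaks or regions only. The signal of a single peak is the authors' value from the pooled list and has no replicate error; ranks in the replicates are given for a part of the named peaks.

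On the nuclear chromosomes, the peaks with the highest signal lay near genes of several kinds. The first, on chromosome III at 154291 to 154460, had a signal of 174 and no protein-coding transcription start site (TSS) within 2000 bp. The second lay in the promoter of srz-62, a chemoreceptor family gene, on chromosome IV at 3899942 to 3900138, with a signal of 172, rank 26 in replicate 1 and rank 21 in replicate 2. Both fell within the 25 peaks of highest signal, of which the other 23 lay on mitochondrial DNA. The leading 25 nuclear peaks, a set chosen after the mitochondrial peaks had been seen, ran in signal from 75.1 to 174, and 21 of them had a protein-coding TSS within 2000 bp. The lysozyme gene lys-8 had a promoter peak on chromosome II at 5585851 to 5586170 with a signal of 111, ranked 32 in both replicates. The gene psa-3, a Meis-related gene that acts in the division of the T blast cell, had a promoter peak on chromosome X at 15408659 to 15408978. Its signal was 103, and it ranked 33 in replicate 1 and 31 in replicate 2. Promoter peaks also lay at irg-4, an infection response gene (signal 96.9), the C-type lectin gene clec-78 (signal 93.1), B0507.3 (signal 84.5) and the fatty acid desaturase gene fat-4 (signal 78.4), whose neighbour fat-3 was also within reach. Outside promoters, leading peaks lay near T24E12.13 and T24E12.1, fbxc-29 and fbxc-33, F14E5.8, R02D5.1, the beta-tubulin gene tbb-2, F21F8.5 and the aspartyl protease gene asp-6, and chdp-1. Further ones lay near nspc-17 and nspc-18, mdl-1, the xanthine dehydrogenase gene xdh-1, T13B5.9, C52E2.3 and C52E2.2, T20B3.1, and the Mediator gene mdt-4 with ZK546.19.

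Most mitochondrial peaks, 23 of 25, had a higher signal than every nuclear peak. The 25 lay on 15 distinct intervals of the 13794 bp molecule, held the first 23 ranks, and ran in signal from 129 to 3682. The highest lay between MtDNA 5345 and 5865 at COX3, and the next, with a signal of 3515, between 12656 and 13391 in ND5. The nearest genes of the leading 23 were COX3, ND5, ATP6, ND3, ND4, CYTB, COX1, ND1, COX2, ND4L, ND6 and ND2, which are all 12 protein-coding genes of the molecule. Regions covered 64.7% of the molecule in replicate 1 and 51.9% in replicate 2.

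Most nuclear peaks carried a GATA site at their summit. The consensus WGATAR, bound by GATA-family zinc finger factors, occurred within 50 bp of the summit in 269 of the 303 nuclear thresholded peaks (88.8%, 95% interval 84.7 to 92.1) and in 9 of the 25 mitochondrial ones (36%). Over all 328 peaks the share was 84.8%, against 35.9% of 1640 GC-matched windows from the other pooled regions (odds ratio 9.92, adjusted exact p = 3.69e-61, two-sided Fisher's exact test). The element CTTATCA, which contains such a site on the other strand, occurred in 49.7% against 10.8% (odds ratio 8.17, adjusted exact p = 5.50e-52). With flanks 1000 bp away as controls the odds ratio of WGATAR was 20.1 and that of CTTATCA 32.9, and the latter was 12.9 without replicate 1. The splice acceptor-like TTTTCAG was less frequent at the peaks, at 3.35% against 9.33% (odds ratio 0.337, adjusted exact p = 7.78e-04). That last call was lost without replicate 2 (odds ratio 0.578, adjusted exact p = 0.0590, the highest of 7 alternatives that began at 7.31e-06). The controls were matched on GC content and not on position. Introns held 16.2% of the peak summits and 33.05% of the other regions, so this difference was not separated from position. The remaining 11 of the 14 motifs did not pass. The T-box element TCACACC came nearest, with 3.05% against 1.22% (odds ratio 2.55, adjusted exact p = 0.0802). It passed in 4 of 7 alternatives, and its odds ratio was 7.08 without replicate 1 (adjusted exact p = 2.34e-04, with a range up to 0.393). The E-box CACGTG, at 3.35% against 1.83% (odds ratio 1.86, adjusted exact p = 0.249), passed only without replicate 1 (odds ratio 2.78, adjusted exact p = 0.0162, with a range up to 0.941). For the GAGA, KLF/SP, TCF/POP-1, homeobox, nuclear receptor, FOXO, BLMP-1, E2F and TATA elements the odds ratios ran from 0.537 to 1.32 and the lowest adjusted exact p was 0.372.

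The GATA site share followed the order of the nuclear regions by signal. In the pooled list it was 89% in the first 100 regions, 91% in the next 100, 60.2% from rank 501 to 1000, and 22.4% from rank 10001 on. It fell from 93% in the first 100 to 22.6% from rank 10001 on in replicate 1, and from 87% to 23.03% in replicate 2. At the nuclear thresholded peaks the site nearest the summit lay at a median distance of 14 bp, and 208 of the 303 had a site within 25 bp (68.6%). These descriptions were chosen after the motif result was seen.

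**Figure D1:**
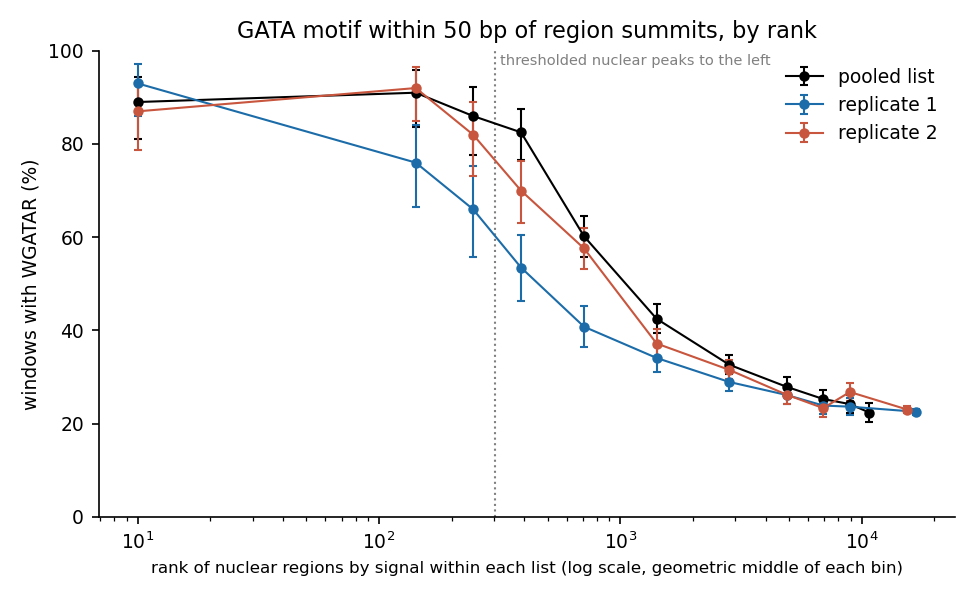
Share of windows (%) with the GATA consensus WGATAR within 50 bp of the summit, for nuclear regions in bins of rank by signal (log axis) in the pooled list and in each replicate; bars are exact 95% binomial intervals. The share is 89% in the first 100 pooled regions and 22.4% from rank 10001 on.

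**Figure D2:**
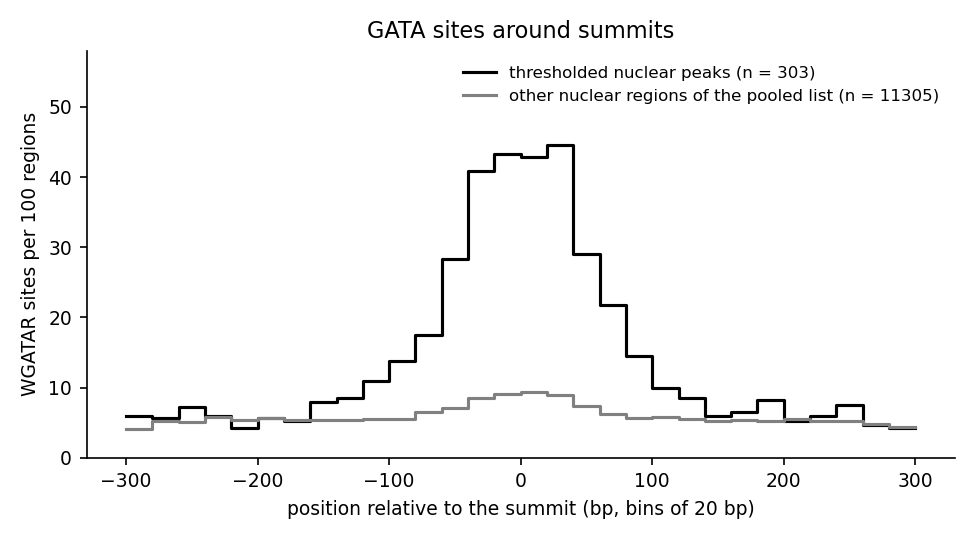
WGATAR sites per 100 regions in bins of 20 bp, by position relative to the summit (bp), for the 303 nuclear thresholded peaks and the other 11305 regions of the pooled list. The sites of the thresholded peaks gather around the summit.

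Thresholded peaks lay at promoters more often than the other pooled regions did, and in introns less often. Summits of 141 of 328 peaks lay within a promoter (42.99%, 95% interval 37.6 to 48.5), against 20.7% of the other 11305 regions (odds ratio 2.89, adjusted exact p = 2.26e-18, Fisher's exact test). In introns the shares were 16.2% and 33.05% (odds ratio 0.390, adjusted exact p = 3.78e-11). Intergenic positions took 32.01% of the peaks, against 35.5% of the other regions, and did not differ by the test (adjusted exact p = 0.297). The UTR, coding exon and other gene classes each took 2.74% to 3.05% of the peaks and did not pass either. These shares include the 25 mitochondrial peaks, while 0 of the other regions were mitochondrial. Mitochondrial peaks such as those in ND5 and ND1 stood among the few in coding exons, so the coding exon share over all 328 peaks does not describe nuclear peaks. Coding exons (odds ratio 0.620, adjusted exact p = 0.297) passed in 4 of 7 alternatives, with an odds ratio of 0.359 without replicate 1 and 0.425 without replicate 2.

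**Figure D3:**
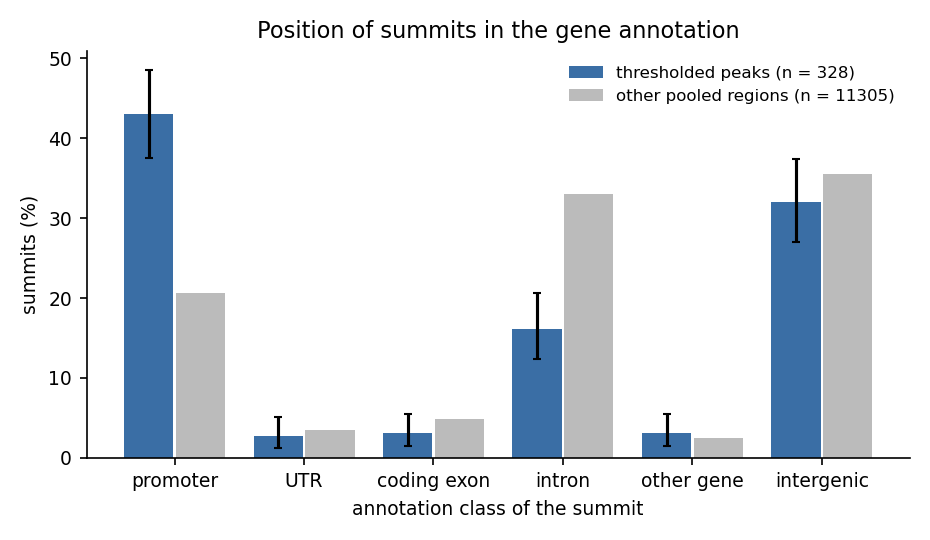
Share of summits (%) in each annotation class, for the 328 thresholded peaks with exact 95% binomial intervals and for the other 11305 pooled regions. Promoters hold 42.99% of the peaks and 20.7% of the other regions, and introns 16.2% and 33.05%.

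By chromosome, all 25 mitochondrial regions of the pooled list were thresholded peaks (adjusted exact p = 5.05e-39). Chromosome II held 62 peaks, 18.9% against 13.2% of the other regions (odds ratio 1.53, adjusted exact p = 0.0136), and chromosome X held 51, 15.5% against 21.04% (odds ratio 0.691, adjusted exact p = 0.0367). Chromosomes I, III, IV and V did not pass, with odds ratios from 0.753 to 1.01. Without replicate 1 neither chromosome II (odds ratio 1.33) nor chromosome X (odds ratio 0.894) passed, nor did either against chromosome length. With nuclear regions alone, chromosome II passed (odds ratio 1.69) and chromosome X did not (odds ratio 0.759).

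The thresholded peaks named 237 protein-coding genes, 4.11% of the 5768 genes assigned to any pooled region, and 0 of the 24 gene lists passed Fisher's exact test, with 1 at an unadjusted p under 0.05. That list was the Hox genes and cofactors, with psa-3 and the Meis-family gene unc-62 among its 6 assigned members (odds ratio 11.8, exact p = 0.0226, adjusted exact p = 0.542). Its odds ratio was 4.87 without replicate 1, the lowest of 9 alternatives, and 18.7 with all protein-coding genes as background, the highest; in random draws of regions the number of its members at peaks was 3.11 times the mean of the draws, after 0.5 was added to both. The T cell lineage and male tail list, which is the closest to the known roles of tlp-1, had 2 of 11, psa-3 and egl-27, the latter a gene for a protein related to the NuRD complex (odds ratio 5.22, adjusted exact p = 0.869), with odds ratios from 3.33 to 9.33 over the same 9 alternatives and a ratio of 2.18 to the random draws. The peak of egl-27 lay in an intron on chromosome II at 6842722 to 6843041 with a signal of 40.5, ranked 6786 in replicate 1 and 143 in replicate 2. That of unc-62 lay on chromosome V at 4505392 to 4505711 with a signal of 39.3. The other 9 lists with a member at a peak had adjusted exact p = 1.

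The seam and epidermal regulators had 1 of 14, elt-3, a GATA factor gene of the epidermis (signal 38.4, rank 3878 in replicate 1 and 312 in replicate 2), which was also the 1 of 11 T-box and GATA genes. The intestine genes had 1 of 13, ifb-2, an intermediate filament gene (signal 56.05). Of the 14 body wall muscle genes, act-1 had a peak (signal 63.4); reads shared with the closely similar actin genes were not examined. The cuticle collagens had 1 of 40, col-3, beside col-117 (signal 54.2). The nuclear hormone receptors had 3 of 107, nhr-88, nhr-130 beside nhr-212, and nhr-8 beside mrps-24 (signals 50.8, 43.3 and 41.1). The homeobox genes had 1 of 31, unc-62, and the chromatin regulators 1 of 7, egl-27. The bHLH genes had 1 of 15, mdl-1 (signal 82.5). The other 13 lists had no member at a thresholded peak among 127 assigned genes. They were Wnt signalling, heterochronic, pan-neuronal, neuronal identity, pharynx, germline and P granule, ribosomal protein, histone, translation factor, heat shock and stress, insulin pathway and L1 arrest, cell cycle, and miRNA pathway and Argonaute genes. These lists had 3 to 17 assigned genes each, and 4.11% of all assigned genes were at thresholded peaks. In lists this short, 0 members is no sign of absence.

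Genes for tRNA and rRNA lay near thresholded peaks more often than near other pooled regions, and the excess did not pass the test without the mitochondrial peaks. Within 1000 bp of a tRNA gene lay 30 peaks, 9.15% against 1.51% (odds ratio 6.55, adjusted exact p = 1.35e-13), and 13 lay near an rRNA gene (adjusted exact p = 2.82e-20), the latter all mitochondrial. With nuclear regions alone, 10 of 303 peaks lay near a tRNA gene (3.30% against 1.51%, adjusted exact p = 0.142) and 0 of the 5 classes passed, with 1 at an unadjusted p under 0.05. The peaks of highest signal near tRNA genes were the mitochondrial ones nearest COX3 and ND5, and near rRNA genes the mitochondrial ones nearest ND3 and ND1. The snRNA, snoRNA and miRNA classes had 1, 5 and 3 peaks and did not pass (adjusted exact p = 0.538, 0.321 and 0.321). The snoRNA class passed without replicate 1 (odds ratio 2.45, adjusted exact p = 0.0494, with a range up to 0.827). The snRNA peak lay over the spliced leader gene sls-2.1, near ZK1248.17 and H41C03.3 (signal 62.9). The leading snoRNA peaks lay near ZK546.18 and ZK994.7 (signals 75.1 and 52.2). The leading miRNA peaks lay near cel-mir-8204, at F21A9.1 and F21A9.2, and near cel-mir-60 (signals 64.5 and 44.1).

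The replicates shared their strongest regions far beyond chance. Of the 328 regions of highest signal in replicate 1, 161 were overlapped by the 328 highest of replicate 2 (49.1%), against a median of 0.305% and a highest share of 1.83% in 1000 random draws (one-sided permutation p = 0.001, the smallest that 1000 draws can give). The shared part was 34.3% for the first 1000 regions of each list and 22.9% for the first 5000. The thresholded peaks were called from both replicates together, so that their overlap with each replicate's list is no independent test. Of them, 324 were overlapped by a region of replicate 1 (98.8%, 95% interval 96.9 to 99.7) and 325 by a region of replicate 2 (99.1%, 95% interval 97.4 to 99.8). Of the other 11305 pooled regions, 69.8% and 80.9% were overlapped, a comparison added after the data were seen. The median ranks of the thresholded peaks in the replicates were 190 and 164, and 220 and 251 of them fell within the first 328 of the respective list. Over the whole lists the order was shared weakly. The 8588 overlapping pairs took in 30.5% of the regions of replicate 1 and 35.8% of those of replicate 2, and Spearman's correlation of signal across them was 0.243 (95% bootstrap interval 0.222 to 0.264); regions are not independent replicates. A fit of the irreproducible discovery rate to these pairs placed 307 regions under 0.02, and 268 of the 328 thresholded peaks (81.7%) were overlapped by one of them.

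**Figure D4:**
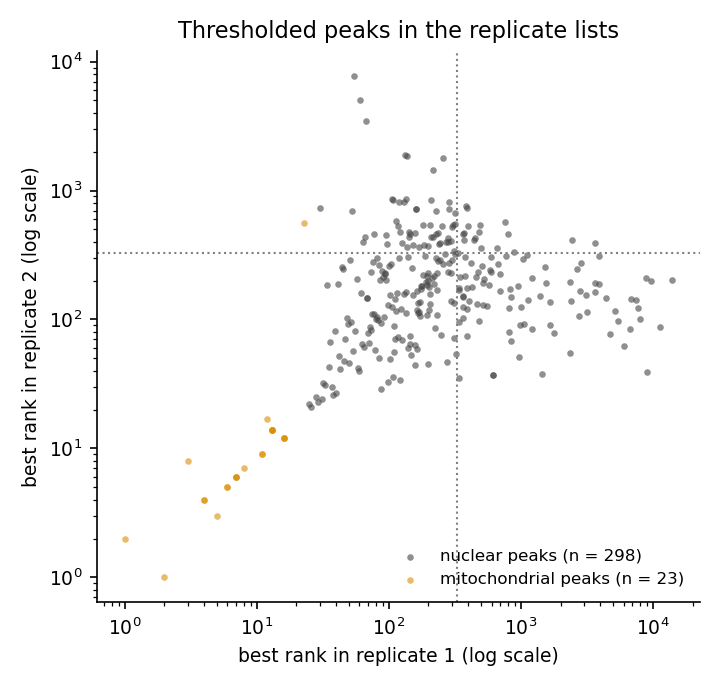
Best rank by signal (log axes) of each thresholded peak in replicate 1 and in replicate 2, for nuclear and mitochondrial peaks overlapped in both; dotted lines mark rank 328. The leading ranks in both replicates are mitochondrial peaks, and 1 mitochondrial peak lies among the nuclear ones in replicate 2.

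The thresholded list depended little on the genome build. The thresholded ce10 list held 320 peaks and that of ce11 328, and 317 of the 328 had a counterpart of the same rank, chromosome and width (96.6%, 95% interval 94.1 to 98.3). Over the 320 compared ranks, paired by rank alone, the signals differed by a median of 0.000406% and at most 0.967%. The unthresholded list of replicate 2 changed more, from 21376 regions on ce10 to 23975 on ce11.

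The tagged gene and the marker gene of the strain were looked up to check the labels. Gene tlp-1, on chromosome IV at 13701208 to 13704082, had 0 regions within 5000 bp in each replicate, the pooled list and the thresholded list. The stretch without a region around it measured 56114 bp in replicate 1, 54115 bp in replicate 2 and 81884 bp in the pooled list. As few regions lay near 7.004% of nuclear protein-coding genes in replicate 1, 9.42% in replicate 2 and 30.9% in the pooled list. The gene unc-119, used as the marker of the transgene, on chromosome III at 10902641 to 10908935, had 12 regions within 5000 bp in replicate 1, 8 in replicate 2 and 8 in the pooled list. As many lay near 1.03%, 3.75% and 0.421% of genes, and 0 of the regions near unc-119 were thresholded peaks. All these counts took in the gene body as well as 5000 bp to either side. Longer genes thus had wider windows, and gene length was not allowed for.

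A stretch of chromosome V, noticed after the data were seen, held the longest run of closely spaced regions in the pooled list and in each replicate. From 10055135 to 10091626 the pooled list held 50 regions with gaps under 3000 bp between neighbours, or 13.7 per 10 kb against 1.16 over the genome; the next longest run held 11. The run held 62 regions in replicate 1 (10049141 to 10091650) and 68 in replicate 2 (10053347 to 10099843). It spans 12 protein-coding genes, among them the nuclear hormone receptor genes nhr-192, nhr-205 and nhr-12, and holds 1 thresholded peak.

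**Figure D5:**
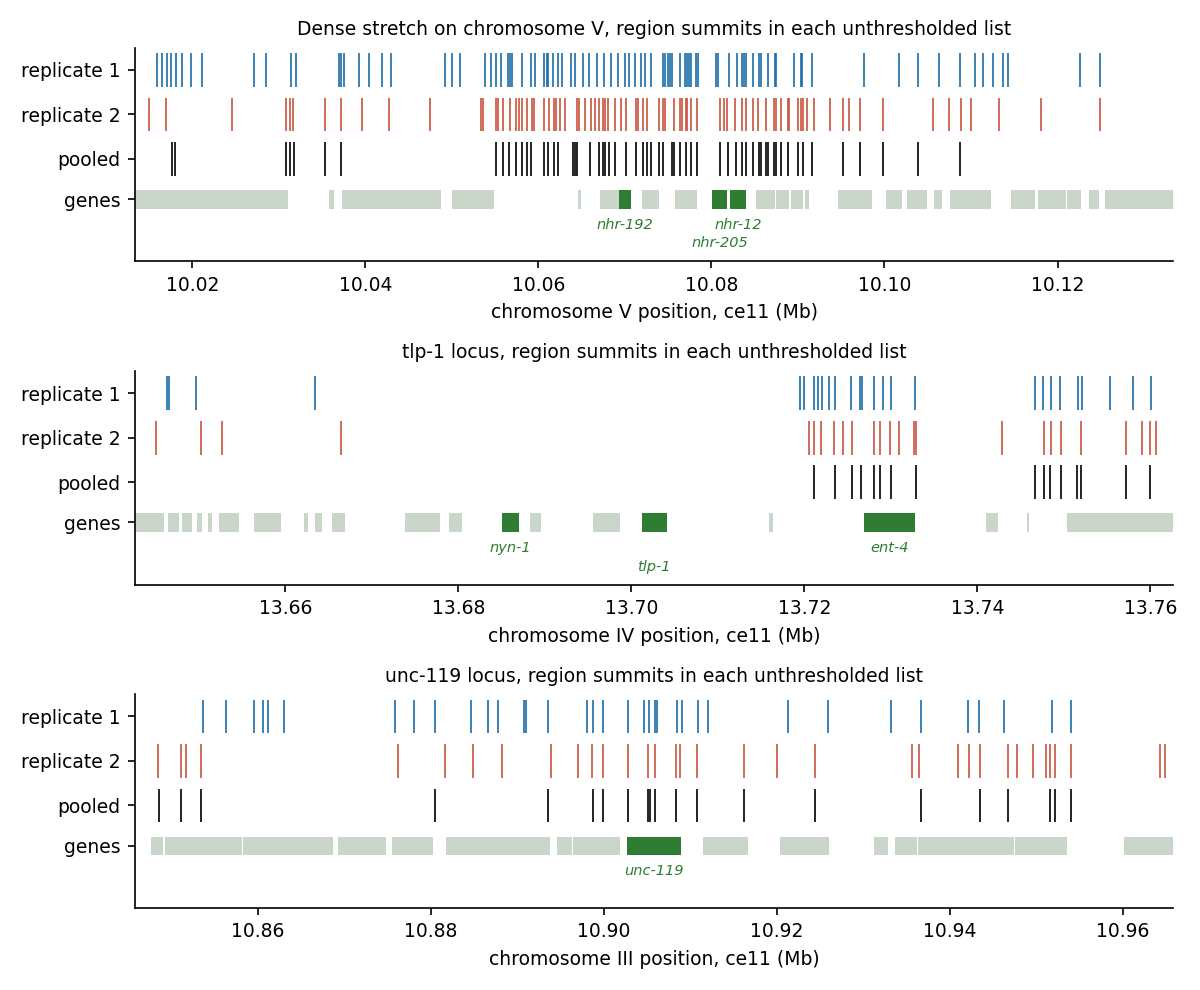
Summits of all regions before thresholding (vertical lines) in replicate 1, replicate 2 and the pooled list, over 60000 bp to either side of the chromosome V stretch, tlp-1 and unc-119 (positions in Mb, ce11), with protein-coding genes as boxes and selected genes in dark green. The chromosome V run holds 62 and 68 regions in the replicates, and no summit lies within 5000 bp of tlp-1.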

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

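The tests on nuclear regions alone, without the chromosome V stretch, within 20000 bp of the marker and tagged genes, and of rank concordance on ce10 or by summits were chosen only after the data were seen. Of 505 alternative values of 73 results under 27 settings, 472 were counted as unchanged and 33 were not. Unchanged meant the same side of the threshold, or a value within the interval of the result reported. Counts were unchanged within 1.5 times the value reported, or at 0 in both. Values that passed neither way counted as unchanged whatever their odds ratio, among them all 240 of the single gene lists. No odds ratio that passed, as reported or in the alternative, changed direction. Of 279 alternative odds ratios without a count of 0, 34 lay on the other side of 1 from the value reported, none of them passing either way. Without replicate 2 they included intergenic positions (0.856 to 1.23), other genes (1.23 to 0.587) and the KLF/SP element (0.854 to 1.84), and in the higher-signal 50% the FOXO element (1.32 to 0.353). The counts of passing position classes (2 to 3) and gene lists (0 throughout 10 alternatives, with 0 to 3 at an unadjusted p under 0.05) and the IDR count (246 to 414) stayed within 1.5 times the value reported or at 0, while the top-region overlap ran from 57% in the top 100 to 34.3% in the top 1000 and 22.9% in the top 5000, each with a permutation p = 0.001, the smallest that the draws can give. With summits within 100 bp, rank concordance was 0.345 and recovery in replicate 1 was 92.7%. That recovery was 94.2% at an overlap of 50% of both regions, and 100% for the higher-signal 50% of the peaks. The count of passing chromosomes, 3 as reported, was 1 to 3 without 1 replicate, 1 with nuclear regions alone, where the mitochondrial molecule is left out by construction, and 1 against chromosome length. The count of passing motifs, also 3, was 2 to 5 without 1 replicate. Non-coding classes passed 0 times with nuclear regions alone, since the mitochondrial peaks are then left out. Between builds, 0 signals matched exactly. Within 20000 bp, tlp-1 had 2 regions in the pooled list, 7 in replicate 1 and 4 in replicate 2, and unc-119 had 20 in replicate 1 and 15 in replicate 2, a wider window holding more by construction. For the other changes the cause was not tested. Gene context on ce10 was not run, and with the depth unknown no limit from depth can be given.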

Other observations

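The tests of gene families, of the number and form of GATA sites, of the motif on mitochondrial summits, of the ends of the chromosome V stretch, of long stretches without regions and of the intestine list as a sign of open DNA were chosen only after the results were seen. Gene families were also taken from the gene names, and none passed its test. Among all families with at least 5 assigned members, a minimum lowered after a first scan had been seen, 0 passed and 5 had an unadjusted p under 0.05 in Fisher's exact test, where chance alone gives at most 6.3 on average. The lysozyme family lys had 3 of 6 assigned members at thresholded peaks, lys-8, lys-2 and lys-1 (odds ratio 23.6, exact p = 0.00125, adjusted exact p = 0.157). The signal was 55.4 at lys-2 and 41.2 at lys-1. Their summits were close together on chromosome V, at 10280318 and 10277691, and the test counted them as separate genes. The cathepsin B family cpr had cpr-3 and cpr-4 (2 of 5, signals 73.8 and 44.9). The desaturase family fat had fat-4 and fat-6, the latter beside ZK822.9 (2 of 5, signals 78.4 and 42.2). The replicates ranked cpr-4 at 847 and 149, and no region of replicate 1 overlapped the peak of fat-6. The C-type lectins clec had 5 of 39, clec-78, clec-63 (beside clec-62), clec-258, clec-265 and clec-51, with signals from 39.2 to 93.1. The peak of clec-51 ranked 1106 in replicate 1 and 319 in replicate 2, and no region of replicate 1 overlapped the peak of clec-258. The F-box family fbxc had fbxc-29 and fbxc-19, the latter beside fbxa-3 of another family (2 of 6, signals 152 and 70.2).

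GATA sites at nuclear peaks were often multiple. Windows with at least 2 sites made up 66.0% of the 303 peaks and 14.7% of 1515 GC-matched controls (odds ratio 11.3, p = 3.37e-71, Fisher's exact test). The form TGATAA took 71.5% of 599 sites at the peaks against 60.7% of 834 control sites (odds ratio 1.62, adjusted exact p = 9.78e-05). The forms AGATAA and AGATAG took smaller shares at the peaks than in the controls (odds ratios 0.665 and 0.510, adjusted exact p = 0.00745 and 0.00971), and TGATAG did not differ by the test (adjusted exact p = 0.467). The base before the site did not pass for any of the 4 bases (lowest adjusted exact p = 0.105, for C); 1 of them had an unadjusted p under 0.05. Of the leading 25 nuclear peaks, 24 carried a site and 17 carried at least 2, the exception being the peak near nspc-17. Sites in the same window are not independent of each other.

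A GATA site stood at most nuclear peaks. The same letters in reversed order, RATAGW, had an odds ratio of 1.42 at the nuclear peaks, against 13.8 for WGATAR, which argues against base composition as the main source. The reversed letters were themselves somewhat more frequent at the peaks, at 28.7% against 22.1% (unadjusted exact p = 0.0169, Fisher's exact test). A site of the form WGATAG followed by A or T also holds RATAGW. The patterns thus overlap, and this excess was not separated from that of the GATA sites. A hypothesis that stays open is that the peaks mark DNA open to many factors in intestinal cells, where GATA factors are known to act. The intestine list, with 1 of 13 assigned members at a peak (ifb-2; odds ratio 1.95, 95% interval 0.0454 to 13.3, adjusted exact p = 1), does not decide it: its odds ratio was 4.34 without replicate 1 and 7.58 without replicate 2, and over 9 alternatives it ran from 0.956 to 7.58 with adjusted exact p from 0.327 to 1. Whether the tagged protein itself reads the site, or sits beside a GATA factor, was not tested.

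For the mitochondrial peaks, the data bear on a pair of explanations. Sites of the tagged protein like those at nuclear peaks are argued against by the motif share of 36% at the 25 summits (95% interval 17.97 to 57.5), which includes the 30.1% of all 13694 windows of the molecule and lies below the 88.8% of nuclear peaks. Reads from the many copies of mitochondrial DNA are a candidate explanation: regions covered 51.9% of the molecule in the replicate with less, just above the bound of 50% set before the test. Binding without a GATA site, and a different share of mitochondrial DNA in the control, stay open. Apart from binding by the tagged protein, no biological explanation was tested, as the design has a single group.

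The dense chromosome V stretch and the empty stretch at tlp-1 may have separate sources, and the single group of the design gives no biological contrast to test. Clustered binding at GATA sites over the chromosome V stretch is argued against by a motif share of 22% in its 50 pooled regions, against 39.2% of 250 regions of like rank elsewhere (odds ratio 0.437, p = 0.0239, Fisher's exact test); binding without such sites was not excluded, and the explanation was narrowed to GATA sites after this value was seen. Extra DNA copies of the stretch in the libraries relative to the control stay open, since ends that differed by at most 8193 bp between replicates would come with any source common to both. The soft-masked share of the 53053 bp stretch around tlp-1 stood at percentile 73.2, close to the bound of 75. Of 3828 overlapping stretches of like share, 0.340% held no region in either replicate, a test added after the first of these values. Their length was set by the empty stretch itself. Only 5 stretches of at least 50000 bp lacked regions in both replicates, so a low share was likely at any soft-masked share. The second value therefore does not decide. The first argues only weakly against soft-masked repeats as the source of the empty stretch. Overlapping stretches are not independent, and whether reads can be placed there was not measured. A duplication in the strain, extra tlp-1 copies in the control, and libraries or a control from another strain than labelled stay open, and would need the reads or the control.

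The empty stretch at tlp-1 was not the only one. Stretches of at least 50000 bp without a region in either replicate numbered 5 in the nuclear genome and held 83 protein-coding genes, 0.416% of them. The one at tlp-1, on chromosome IV from 13666473 to 13719525, held 7 genes and was 41.1% soft-masked. The longest, on chromosome V from 2345628 to 2566000, measured 220373 bp and held 48 genes. Another, on chromosome V from 8804898 to 8905171, held 28 genes; these were 46.7% and 16.9% soft-masked. The remaining stretches, on chromosome III from 7397824 to 7453548 and on chromosome IV from 6666742 to 6735104, held 0 genes and were 88.4% and 82.97% soft-masked.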
